A study of Mus musculus with 6 samples.

How the data were processed

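Bulk RNA sequencing was done on lung tissue of NSG mice killed 5 weeks after orthotopic injection of human MDA-MB-231 cells (Ctrl, 3 libraries) or MDA-MB-231 cells with DPP3 knocked out (DPP3_KO, 3 libraries). Libraries were made from total RNA with a TruSeq kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and the third Ctrl title carries 232 in place of 231, which was read as a slip for the same cell line. The values are TPM that the authors deposited as a single matrix of 56980 genes with Ensembl identifiers, symbols, descriptions and lengths. HISAT2, StringTie and RSEM and the genome build GRCm39 are named in the submitters' processing notes, without versions or the role of each, and the annotation release, strand setting and treatment of human reads are not given in the sources used here. Each deposited TPM column has the same sum, up to rounding, so TPM keeps no depth, and no counting interval or detection floor is given. All value columns of the matrix matched a sample.

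TPM was changed to log2(TPM + 1), and the 15650 genes with a mean of at least 1 TPM over the 6 samples were tested. The comparison DPP3_KO minus Ctrl was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. With 3 samples against 3, an exact permutation test of a single gene cannot go below p = 0.1, so no such test is given. Gene lists were tested with camera (limma) at a preset correlation of 0.01, over lists with at least 5 tested members, and again with an estimated correlation and with fry. Before the data were examined, 51 lists were fixed for lung cell types, tissues that could be dissected with lung, immune cells, RAP1 signalling, Nrf2 and other processes; a list of genes on the sex chromosomes was left out, and 45 of the others had enough tested members. Within each list, adjustment was also made over the list alone.

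The genes named in the text followed a rule also fixed before the data were examined: the 12 largest log2 changes in each direction among called genes whose groups did not overlap, leaving out unnamed gene models and sex-chromosome list genes; the 4 members with the smallest p of each called list and of the 3 RAP1 lists; and Dpp3, Keap1, Nfe2l2, Rap1a, Rap1b, Rap1gap, Sipa1 and Rapgef3. This gave 118 genes, of which 98 passed. A few of these are not reported here. Tcf7, Ighm, Ccl5, Rps7, Lmod1, Synpo2 and the genes named only in the closing section were chosen after their values were seen.

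The alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, TPM rescaled without mitochondrial and haemoglobin genes, limma without the trend, with sample quality weights and with robust estimation, the replicate number as a block, each sample left out in turn, other thresholds, and the other set tests. Added after seeing the data were TPM rescaled without Scgb1a1, median-of-ratios scaling with each library's trend with gene length removed (lowess span 0.3), and each sample left out after median-of-ratios scaling.

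The fit was tested on simulated data made from the real gene means and residual spreads of this comparison after median-of-ratios scaling, with 200 genes changed. On the deposited values many more genes were called (5321 lower), so the rates below do not carry over to that fit. For changes of 1 on the log2 scale, 0 of the 200 genes were called among 15317, with a median estimate of 0.99. For changes of 2, 72.0% were recovered among 15310 genes with 10 false calls, and for changes of 3, 95.0% among 15277 with 8 false calls. Camera called 1 of 45 lists when only the integrin list had been shifted by -1. The simulated genes varied independently of each other, so camera's calls for lists whose members vary together were not tested. When Scgb1a1 alone was given its real shares of 8.33% and 26.1%, the other genes of 14931 tested moved by a median log2 of -0.27, and 0 were called higher or lower, against -0.0015 after median-of-ratios scaling. Gene types for the pseudogene test came from GENCODE release M21, matched by gene identifier. That release describes an earlier genome build than the deposited table, so coordinates were not used here.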

Results

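Gene expression was measured by RNA sequencing in 6 lung libraries from immunodeficient NSG mice, 5 weeks after human breast cancer cells had been placed in the mammary fat pad. MDA-MB-231 is a human triple-negative breast cancer line, and NSG mice lack mature T, B and natural killer cells. In the Ctrl group (n = 3) the tumours came from MDA-MB-231 cells, and in the DPP3_KO group (n = 3) from MDA-MB-231 cells in which DPP3, the gene of dipeptidyl peptidase 3, had been knocked out. The comparison asks how the lung of the host differs when the tumour lacks DPP3, and the title of the series names RAP1 signalling and lung metastasis. The values are TPM for 56980 mouse genes, and each library has the same sum by construction, so the sequencing depth behind them is unknown. Between 22904 and 24477 genes lay above 0 per library. The labels number the replicates without saying that each came from a separate mouse, so the p-values measure the spread between these samples. Pearson correlations of log2(TPM + 1) across genes were 0.916 to 0.957 for pairs within a group and 0.878 to 0.928 for pairs across groups.

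Several ciliated cell, club cell and heart muscle genes were higher in DPP3_KO than in Ctrl lungs as deposited, and most of the alveolar type 1, capillary and alveolar macrophage genes tested were lower. The club cell secretoglobin Scgb1a1 (ENSMUSG00000024653) alone took 8.33% ± 1.58 (SD, n = 3) of all TPM in Ctrl and 26.1% ± 3.84 in DPP3_KO. The deletion was made in the human tumour cells, so the mouse gene Dpp3 (ENSMUSG00000063904) does not check the labels. Dpp3 stood at 28.3 ± 2.24 TPM in Ctrl and 17.7 ± 3.04 in DPP3_KO, a log2 change of -0.66 (limma, Benjamini-Hochberg adjusted p = 0.0343) that became -0.02 after median-of-ratios scaling and 0.01 after quantile normalization. Of 15650 genes tested, 216 were higher and 5321 lower in DPP3_KO as deposited, with a median log2 change over all genes of -0.60. The number of lower genes in each list below is to be read against this share, 5321 of 15650. After median-of-ratios scaling, which brought that median to -0.02, 304 genes were higher and 139 lower, and 187 and 139 of these were also called as deposited. Changes are given as deposited unless stated otherwise, and beside them the number of members of each list that passed after median-of-ratios scaling, which sets each gene against the typical gene. Of the genes named by a fixed rule, 98 passed as deposited, and 60 of these did not pass after that scaling. All log2 changes are on the log2(TPM + 1) scale, which understates those of low genes.

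Most genes of the ciliated airway epithelium rose in DPP3_KO lungs. Of 15 ciliated cell genes, 9 rose over all genes tested, 10 rose adjusted over the list alone, and the median log2 change was 1.06; after median-of-ratios scaling 10 rose over all genes and 15 adjusted over the list alone. Foxj1, the master regulator of motile cilia, rose from 21.5 ± 2.91 TPM to 58.4 ± 11.2 (2.71-fold, log2 change 1.39 ± 0.20 SE, limma adjusted p = 0.0145), and by 2.03 on the log2 scale after median-of-ratios scaling. The cilium genes Cfap126, Tmem212 and Dynlrb2 rose by 1.43, 1.28 and 1.29. The limma camera test of the list gave adjusted p = 2e-22, against adjusted p = 0.222 with an estimated correlation. Of 12 club and secretory airway cell genes 4 rose over all genes and 3 adjusted over the list alone, with a median of 1.25 (camera adjusted p = 5e-16, and adjusted p = 0.222 with an estimated correlation). These were Scgb1a1 (log2 change 1.65, adjusted p = 0.0156), Scgb3a2 (1.85, 0.0157), Scgb3a1 (3.97, 0.0195) and the airway secretory protein gene Bpifb1 (2.54, 0.0490). After median-of-ratios scaling Scgb1a1 stood at 2.32 with adjusted p = 0.0515 and Bpifb1 at 3.18 with adjusted p = 0.0944, while Scgb3a2 and Scgb3a1, 2 of the 12 members, still passed, and adjusted over the list alone 12 of 12 rose. Ctrl replicate 1 held 45.0 TPM of Scgb3a1, against 325 and 470 in the other Ctrl libraries and 1585 to 4480 in DPP3_KO.

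Some striated muscle genes rose as well. Of 15 cardiac and skeletal muscle genes, 6 rose over all genes and 9 adjusted over the list alone, with a median log2 change of 1.17, and after median-of-ratios scaling 7 rose over all genes and 11 adjusted over the list alone (camera adjusted p = 3.8e-20, and adjusted p = 0.222 with an estimated correlation). The cardiac troponin genes Tnnt2 and Tnni3 rose from 139 ± 23.6 to 420 ± 68.4 TPM and from 95.2 ± 23.2 to 281 ± 29.2 TPM, log2 changes of 1.59 and 1.58 (limma adjusted p = 0.0145 for both). Sln, which encodes the calcium pump regulator sarcolipin, rose by 1.57, Myh6, the atrial myosin heavy chain gene, by 1.17, and Mb, the myoglobin gene, by 2.10. In adipose tissue genes, which could come from fat dissected with the lung, 1 of 9 rose and 1 fell, 1 rose adjusted over the list alone, and 1 rose and 0 fell after median-of-ratios scaling (camera adjusted p = 1.1e-05, up, and adjusted p = 0.507 with an estimated correlation). Cidea rose by 1.22, whereas the lipase gene Lipe was lower by -0.69 as deposited (adjusted p = 0.0446), -0.05 after median-of-ratios scaling and 0.07 once the length trend was also removed. Cfd and Plin4, at log2 changes of 1.40 and 0.37, did not pass. The mean log2(TPM + 1) of the adipose list was 4.04 in DPP3_KO replicate 1. In DPP3_KO replicates 2 and 3 it was 2.67 and 2.47, within the Ctrl range of 2.39 to 2.99.

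**Figure D1:**
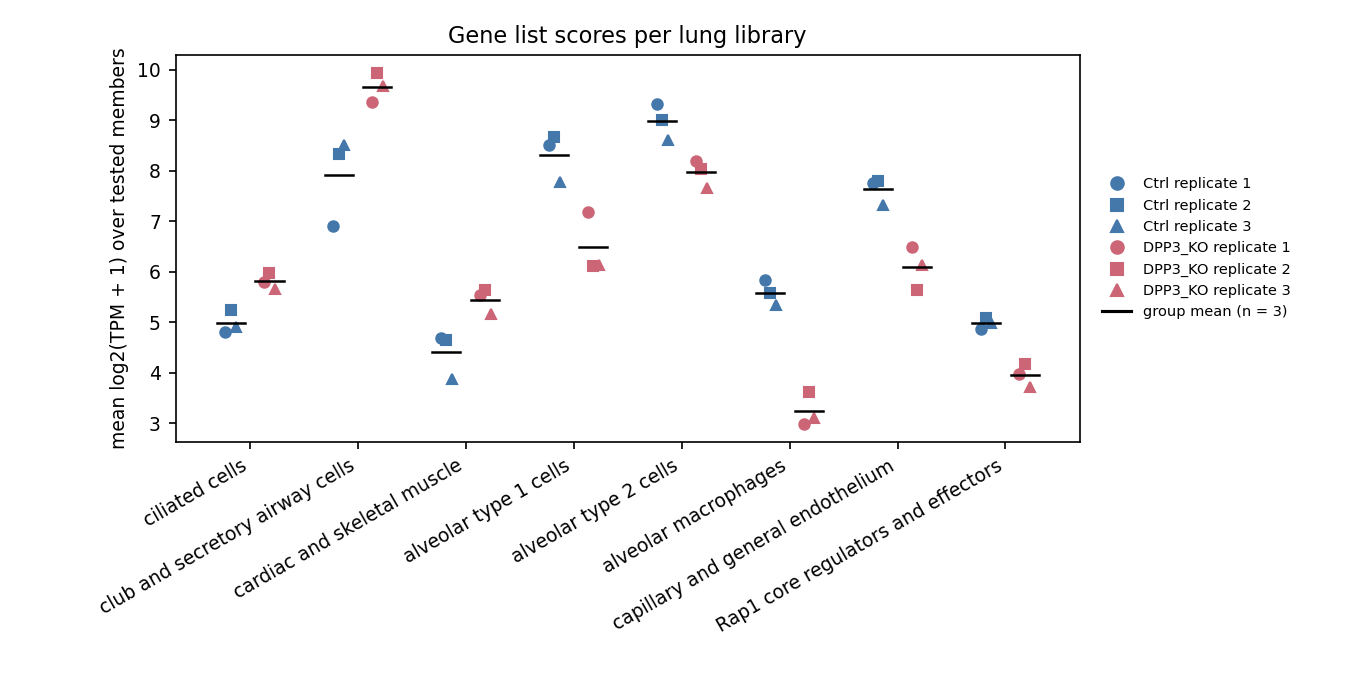
Mean log2(TPM + 1) over the tested members of 8 gene lists in each of the 6 lung libraries. Blue points are Ctrl, red points DPP3_KO, marker shapes the replicate numbers, and black lines group means (n = 3). The ciliated score averaged 4.98 in Ctrl and 5.81 in DPP3_KO, and the alveolar macrophage score 5.59 and 3.23.

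Alveolar macrophage genes showed the largest median fall of the 45 lists tested. Of 16 members, 12 fell over all genes and 12 adjusted over the list alone, with a median log2 change of -2.19, and after median-of-ratios scaling 7 fell, and 12 adjusted over the list alone, with a median of -1.59. The mannose receptor gene Mrc1 fell from 47.6 ± 2.46 to 9.43 ± 0.397 TPM (log2 change -2.22 ± 0.16 SE, limma adjusted p = 0.00449) and stayed called after median-of-ratios scaling at -1.59. Atp6v0d2, a subunit of the vacuolar proton pump, fell from 37.7 ± 11.3 to 1.63 ± 0.188 TPM, Krt79 from 27.9 ± 12.9 to 0.420 ± 0.191 TPM and Ear1 from 57.1 ± 11 to 3.23 ± 2.15 TPM. Ear1, Ear2 and Ear10 are near-identical eosinophil-associated ribonuclease genes, whose reads can be shared, so the value of each is uncertain. Camera gave the list adjusted p = 3.2e-05, and adjusted p = 0.555 with an estimated correlation.

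Most genes of alveolar type 1 cells, the thin gas-exchange epithelium, also fell. Of 12 members 10 fell, and 10 adjusted over the list alone, with a median of -1.94 as deposited and -1.29 after median-of-ratios scaling, where 2 still passed over all genes and 8 adjusted over the list alone. Pdpn fell from 77.2 ± 19.4 to 19.3 ± 2.38 TPM (log2 change -1.92, limma adjusted p = 0.0144), as did Emp2 (-2.30), Clic5 (-2.46) and the caveolin gene Cav1 (-2.29). Camera gave adjusted p = 0.00223, and adjusted p = 0.620 with an estimated correlation. In the surfactant-producing alveolar type 2 cells 6 of 15 members fell, and 12 adjusted over the list alone, with a median of -0.89, and 0 passed after median-of-ratios scaling. Camera did not call this list as deposited (adjusted p = 0.0778) or after median-of-ratios scaling (0.0564), but called it down after quantile normalization (adjusted p = 0.000378, median -0.61), without a filter (0.0108) and with the length trend removed (0.0207).

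Most capillary endothelial genes fell in the same lungs. Of 21 members 17 fell, and 18 adjusted over the list alone, with a median of -1.65 (camera adjusted p = 6.5e-05, and adjusted p = 0.620 with an estimated correlation). After median-of-ratios scaling 3 members fell, and 11 adjusted over the list alone, with a median of -0.99. Cdh5, which encodes the endothelial adherens junction cadherin, fell from 319 ± 62.7 to 55.4 ± 20.0 TPM (log2 change -2.55 ± 0.29 SE, limma adjusted p = 0.0144) and remained called at -1.89 after median-of-ratios scaling. The transcription factor gene Erg (-1.79), Pecam1 (-1.75) and the adrenomedullin receptor gene Calcrl (-2.76) fell too. Of 26 endothelial junction and barrier genes 21 fell, and 22 adjusted over the list alone, among them Arhgef15 (-1.54) and S1pr1 (-1.45), with 1 passing after median-of-ratios scaling and 11 adjusted over the list alone (camera adjusted p = 0.000117, and adjusted p = 0.620 with an estimated correlation). Of 9 aerocyte genes 5 fell, and 7 adjusted over the list alone (camera adjusted p = 0.122), with 0 passing after median-of-ratios scaling. Among 8 lymphatic endothelial genes 5 fell, and 5 adjusted over the list alone (camera adjusted p = 0.116). Large-vessel endothelium had 2 of 9 genes lower, and 2 adjusted over the list alone (camera adjusted p = 0.848). In each of these 2 lists 1 gene was lower after median-of-ratios scaling.

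RAP1 is a small GTPase that controls integrin adhesion and endothelial junctions, and most of its core regulators and effectors tested were lower in DPP3_KO lungs as deposited. Of 46 tested members 31 fell, and 35 adjusted over the list alone, with a median log2 change of -0.99 as deposited. Relative to other genes the fall was smaller: after median-of-ratios scaling the median was -0.39 (-0.26 with the length trend also removed), with 1 member called over all genes and 4 adjusted over the list alone. Camera gave adjusted p = 0.000611 as deposited and 4.2e-05 after median-of-ratios scaling, against adjusted p = 0.620 and 0.182 with an estimated correlation. Tln1, which encodes the integrin activator talin, fell from 133 ± 7.91 to 48.2 ± 8.72 TPM (log2 change -1.46 ± 0.19 SE, limma adjusted p = 0.0145) and stood at -0.80 after median-of-ratios scaling (adjusted p = 0.0544). Rapgef4, a cAMP-regulated RAP1 activator, fell from 39.7 ± 13 to 7.63 ± 2.40 TPM and was the member called after both scalings (-2.22 and -1.61). Rasgrp3, another RAP1 activator (-2.16), and Arap3 (-1.16) also fell. The capillary endothelial list stood at a median of -1.65 in the same libraries.

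The RAP1 genes themselves did not pass. Rap1a stood at 111 ± 31.3 TPM in Ctrl and 74.4 ± 15.5 in DPP3_KO (log2 change -0.56, limma adjusted p = 0.120; 0.10 after median-of-ratios scaling), and Rap1b at 231 ± 82.4 and 130 ± 63.8 TPM (-0.87, adjusted p = 0.104). The activator gene Rapgef3 was lower as deposited (-0.70, adjusted p = 0.0270), at -0.05 after median-of-ratios scaling, and the GTPase-activating protein genes Sipa1 and Rap1gap stood at -0.88 (adjusted p = 0.0498) and -0.65 (adjusted p = 0.0546), or -0.23 and -0.00088 after median-of-ratios scaling. With the length trend also removed, Rapgef3, Rap1gap and Rap1a were above 0 at 0.09, 0.16 and 0.06. Among 72 genes of RAP1 downstream signalling 36 fell, and 40 adjusted over the list alone, with Adcy4 (-1.76), Ctnnd1 (-1.42) and Plcg1 (-1.27) among them. Camera called this list as deposited (adjusted p = 0.00704, and adjusted p = 0.620 with an estimated correlation), although 0 members passed after median-of-ratios scaling, and not with the length trend removed (adjusted p = 0.0745) or at a mean of at least 5 TPM (0.0721). Of 52 RAP1 ligands and receptors 17 fell, near the share over all genes (5321 of 15650), and 17 fell adjusted over the list alone. After median-of-ratios scaling 1 was lower, and 7 adjusted over the list alone. Camera did not call the list (adjusted p = 0.359). Its leading members were Hgf, the hepatocyte growth factor gene (-2.20), Flt4 (-1.63), Pdgfd (-2.06) and the angiopoietin receptor gene Tek (-2.49), and Hgf was the 1 that still passed after median-of-ratios scaling, at -1.69.

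**Figure D2:**
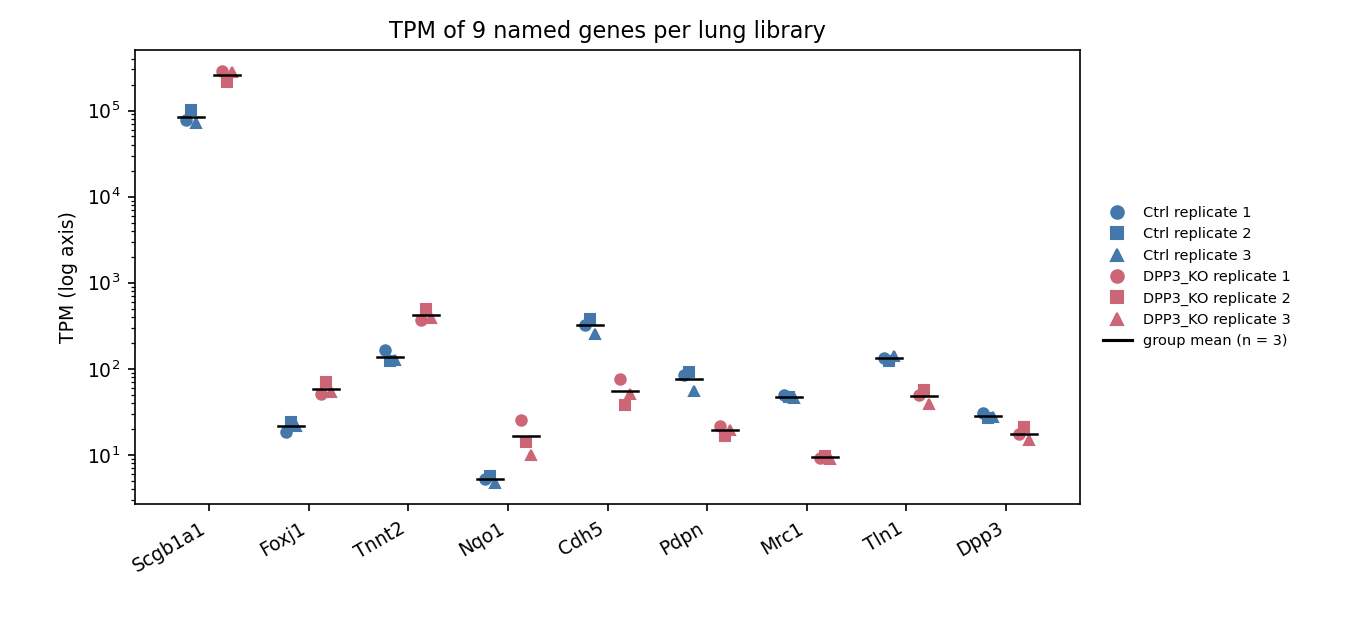
TPM of 9 named genes in each of the 6 lung libraries, on a logarithmic axis. Blue points are Ctrl, red points DPP3_KO, marker shapes the replicate numbers, and black lines group means (n = 3). Foxj1 averaged 21.5 TPM in Ctrl and 58.4 in DPP3_KO, and Mrc1 47.6 and 9.43.

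Many adhesion and antiviral genes were lower in DPP3_KO as well. Of 37 integrin and focal adhesion genes 28 fell, and 32 adjusted over the list alone, including Lims1 (-1.37) and the collagen receptor gene Itga2 (-1.52); after median-of-ratios scaling 0 passed over all genes and 8 fell adjusted over the list alone, with a median of -0.49, or -0.28 with the length trend also removed. Camera gave adjusted p = 0.0003, and adjusted p = 0.620 with an estimated correlation, in libraries in which the capillary list lay at -1.65 and the alveolar macrophage list at -2.19. Of 38 interferon response genes 21 fell, and 26 adjusted over the list alone (camera adjusted p = 0.00069, and adjusted p = 0.620 with an estimated correlation). Ifit3 fell from 105 ± 11.7 to 31.7 ± 10.1 TPM (log2 change -1.74), and Ifit3b (-1.76) and Ifit1 (-1.30) fell with it. Of 21 antigen presentation genes 11 fell, and 17 adjusted over the list alone, with B2m at -1.32, H2-Q6 at -1.70, H2-Q4 at -1.15 and H2-Q7 at -1.39 (camera adjusted p = 0.00775, and adjusted p = 0.620 with an estimated correlation). In both lists 0 members passed over all genes after median-of-ratios scaling, with 12 interferon response and 0 antigen presentation genes lower adjusted over the list alone, and the H2-Q genes are close copies whose reads can be shared.

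A few antioxidant enzyme genes rose in DPP3_KO. Of 30 targets of Nrf2, the transcription factor held down by Keap1, 4 rose, 1 fell and 25 did not pass, with a median log2 change of -0.02, and 2 rose adjusted over the list alone. After median-of-ratios scaling 5 rose, and 9 adjusted over the list alone, with a median of 0.63. Nqo1, the quinone reductase gene, rose from 5.24 ± 0.537 to 16.4 ± 7.83 TPM (log2 change 1.39 ± 0.32 SE, limma adjusted p = 0.0214). The glutathione transferase genes Gsta1, Gsta4 and Gsta3 rose by 1.60, 0.97 and 0.85, and Gsta1 has close copies that can share its reads. The club cell list stood at a median of 1.25 in the same libraries. Camera called the antioxidant list up against other genes (adjusted p = 7.6e-08, and adjusted p = 0.355 with an estimated correlation), while fry gave adjusted p = 0.748 as deposited and 0.00747, up, after median-of-ratios scaling. Keap1 and Nfe2l2 did not pass, at -0.58 (adjusted p = 0.0584) and -0.45 (adjusted p = 0.132) as deposited and 0.05 and 0.21 after median-of-ratios scaling.

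Camera also called the ribosomal protein and mitochondrial lists up against other genes, although few of their members passed over all genes. After median-of-ratios scaling the medians of the ribosomal protein, nuclear oxidative phosphorylation and mitochondrially encoded lists were 0.62, 0.56 and 0.92. With the length trend also removed they were smaller, at 0.34, 0.31 and 0.65. Of 78 ribosomal protein genes 0 rose and 5 fell, with 0 adjusted over the list alone, and 1, Rps7, rose after median-of-ratios scaling (adjusted p = 0.0420). The median was -0.05 as deposited, 0.62 after median-of-ratios scaling and 0.14 after quantile normalization (camera adjusted p = 8.3e-10, and adjusted p = 0.620 with an estimated correlation). Rpl3 (-0.65), Rpl10 (-0.68), Rpl31 (-0.78) and Rpl30 (-0.64) fell as deposited, and after median-of-ratios scaling stood at 0.01, -0.01, -0.12 and 0.03. Of 74 nuclear oxidative phosphorylation genes 2 fell, with 0 adjusted over the list alone, and after median-of-ratios scaling 3 rose over all genes and 24 adjusted over the list alone (camera adjusted p = 8.1e-07, and adjusted p = 0.620 with an estimated correlation). Ndufs8 (-0.75) and Ndufa9 (-0.53) fell, though Ndufa9 stood at 0.12 after median-of-ratios scaling. Sdha and Ndufb2, at -0.65 and -0.64 as deposited and 0.00042 and 0.014 after median-of-ratios scaling, did not pass. Of 13 mitochondrially encoded genes 1 rose, mt-Nd6 by 0.68, and 0 rose adjusted over the list alone, with a median of 0.25 as deposited and 0.92 after median-of-ratios scaling, where 1, mt-Nd1, rose over all genes and 8 adjusted over the list alone (camera adjusted p = 7.6e-08, and adjusted p = 0.346 with an estimated correlation). Camera's call of this list ended after quantile normalization (adjusted p = 0.0691, median 0.23). mt-Nd1 (0.49), mt-Co1 (0.50) and mt-Nd3 (-0.59, or 0.07 after median-of-ratios scaling) did not pass as deposited.

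Inflammatory lists gave few changed genes, and after median-of-ratios scaling 0 members of the neutrophil, NF-kB, pre-metastatic niche and immediate early lists passed over all genes. Of 21 neutrophil genes 0 passed over all genes or adjusted over the list alone, and camera's call (adjusted p = 0.000147, up) ended after median-of-ratios scaling (adjusted p = 0.392) and with an estimated correlation (adjusted p = 0.620). Hdc (-0.59), Csf3r (-1.10), Trem1 (-0.72) and Ly6g (-1.04) all lay within the spread between libraries, and Hdc stood at 0.06 after median-of-ratios scaling. Of 31 NF-kB and acute inflammation genes 1 rose and 3 fell, and 1 fell adjusted over the list alone (camera adjusted p = 0.000248, up, and adjusted p = 0.620 with an estimated correlation; 0.0633 after median-of-ratios scaling). The chemokine gene Ccl20 rose by 1.48, while Icam1 (-1.43), Nfkb1 (-0.75) and Il1a (-1.37) fell. Of 33 pre-metastatic niche genes 0 rose and 5 fell, and 5 fell adjusted over the list alone, although camera's direction was up (adjusted p = 0.00061, and adjusted p = 0.620 with an estimated correlation; 0.451 after median-of-ratios scaling). Among them were Cxcl12 (-1.28), Tlr3 (-1.51) and the fibronectin gene Fn1 (-1.23). Of 27 immediate early genes 4 fell, Jun (-0.77), Klf4 (-1.01), Nr4a1 (-1.39) and Klf6 (-0.61, or 0.05 after median-of-ratios scaling), and 0 adjusted over the list alone. After median-of-ratios scaling 3 rose and 0 fell adjusted over the list alone. Camera gave adjusted p = 0.0341, up, against 0.620 with an estimated correlation and 0.244 after quantile normalization. Of 16 smooth muscle and pericyte genes 1 rose and 5 fell, the same numbers adjusted over the list alone. After median-of-ratios scaling 2 rose over all genes, Lmod1 and Synpo2, and 0 fell, while 5 rose and 2 fell adjusted over the list alone. As deposited Gucy1a1 (-1.66), Trpc6 (-1.42), Postn (-1.71) and Notch3 (-1.64) were lower, with adjusted p of 0.117, 0.148, 0.205 and 0.186 after that scaling (camera adjusted p = 0.00162, up, and adjusted p = 0.620 with an estimated correlation; 0.138 after median-of-ratios scaling). Of 9 mesothelial genes 0 passed over all genes, adjusted over the list alone or after median-of-ratios scaling (camera adjusted p = 0.000623, up, and adjusted p = 0.620 with an estimated correlation), and Krt19, Upk1b, Gpm6a and Muc16 stood at -0.43, 0.78, -0.44 and 0.47, with Krt19 and Gpm6a at 0.23 and 0.20 after median-of-ratios scaling.

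Camera did not call the remaining lists as deposited, and their counts of lower genes stand beside 5321 of 15650 over all genes. Among stromal lists, 0 of 18 fibroblast genes passed either way (camera adjusted p = 0.261), 15 of 50 extracellular matrix genes fell, and 15 adjusted over the list alone (0.261), and 11 of 35 matrix remodelling enzymes fell, and 11 adjusted over the list alone (0.773). Among blood and immune cell lists, 6 of 20 monocyte and interstitial macrophage genes fell, and 6 adjusted over the list alone (0.377). Dendritic cell genes were mixed, with 3 of 12 higher and 3 lower, or 3 and 4 adjusted over the list alone (0.0552). Of 12 erythroid genes 1 fell, and 1 adjusted over the list alone (0.359), of 11 platelet genes 2 and 2 (0.848), and of 5 thymus and lymph node stroma genes 1 and 1 (0.261). Among process lists, glucocorticoid-induced genes had 3 of 15 lower, and 3 adjusted over the list alone (0.0695), heat shock genes 6 of 21 and 5 (0.0959), sterol and fatty acid synthesis 12 of 25 and 14 (0.261), complement and coagulation 4 of 28 and 4 (0.261), hypoxia and glycolysis 8 of 30 and 6 (0.359), cell cycle 7 of 25 and 7 (0.359), circadian clock 8 of 17 and 8 (0.956), and genes abundant in mesenchymal carcinoma cells of the MDA-MB-231 type 7 of 17 and 7 (0.789). Of 14 renin-angiotensin genes 6 fell, and 8 fell and 1 rose adjusted over the list alone (0.948). Fewer members of these lists passed after median-of-ratios scaling: extracellular matrix had 2 genes lower, complement and coagulation 1 lower, matrix remodelling enzymes and monocytes 1 higher each and 0 lower, dendritic cells 1 higher and 2 lower, and the other lists of this group 0. For fibroblasts, monocytes, matrix remodelling enzymes, large-vessel endothelium, platelets, erythroid cells and the circadian clock, camera's direction was up while the list median lay below that of all genes. After median-of-ratios scaling camera also called aerocytes (adjusted p = 0.0258), lymphatic endothelium (0.0282), extracellular matrix (0.0165) and cell cycle genes (0.0429) down and heat shock genes up (0.0188), 0 of them with an estimated correlation. Lists of T cells, B cells, natural killer cells, mast cells and cartilage had 3, 4, 1, 4 and 3 tested members, too few for camera, with 1, 1, 0, 2 and 0 lower over all genes, 1, 2, 0, 2 and 0 adjusted over the list alone, and 0 after median-of-ratios scaling. The highest T cell gene, Tcf7, averaged 5.69 TPM over all libraries, the highest B cell gene, Ighm, 7.86 and the highest natural killer cell gene, the chemokine gene Ccl5, 23.8.

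Among the largest single-gene rises, besides Scgb3a1, the acute-phase gene Orm2 rose from 1.47 ± 0.581 to 24.1 ± 18.4 TPM (log2 change 2.93, limma adjusted p = 0.0246), and Orm1 rose by 2.29. Sult1d1, a sulfotransferase gene, rose from 10.6 ± 6.22 to 59.4 ± 16.7 TPM, and the nuclear long non-coding RNA Malat1 from 186 ± 26.4 to 1009 ± 462 TPM. Calca, the gene of calcitonin gene-related peptide, rose by 1.98, the chemokine gene Ccl22 by 2.23, AU040972 by 2.16 and Rpgrip1 by 1.96. Orm1, Orm2, Ccl22 and Bpifb1 no longer passed after median-of-ratios scaling, with adjusted p = 0.0663, 0.0699, 0.0682 and 0.0944 at larger log2 changes. Orm1 and Orm2 are close copies and may share reads. The table holds 2 entries with the symbol Nnt. The entry ENSMUSG00000116207 stood at 0.02, 0 and 0 TPM in the Ctrl libraries and 9.41, 5.31 and 6.37 TPM in DPP3_KO (log2 change 2.96, limma adjusted p = 0.00917), and the reads of the 2 entries may be divided between them. This entry alone therefore does not show a rise of Nnt as a whole.

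Ribonuclease genes and pseudogenes made up most of the largest falls. Ang5 fell from 82.7 ± 22.5 to 2.08 ± 1.72 TPM (log2 change -4.87, limma adjusted p = 0.00879), Ear10 from 62.5 ± 18.3 to 1.76 ± 1.03 TPM and Ear2 from 1235 ± 145 to 137 ± 107 TPM, with the pseudogene Ear-ps2 at -4.10. The other pseudogenes were Rpl35a-ps3 (-5.58), Rpl31-ps9 (-3.86), Rps12-ps10 (-3.45), Rps12-ps19 and Ptges3-ps. Ptges3-ps stood at 37.6, 20.2 and 25.9 TPM in the Ctrl libraries and was listed at 0 in each DPP3_KO library, and Rps12-ps19 stood at 21.8, 3.55 and 36.8 TPM and was also listed at 0. Pseudogene values are uncertain because their reads resemble those of the parent genes, and 4 of these genes (Rpl35a-ps3, Rps12-ps19, Rpl31-ps9 and Rps12-ps10) did not pass after median-of-ratios scaling, with adjusted p of 0.0515 to 0.114.

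As deposited, the counts fell most without Ctrl replicate 1 (1 gene higher and 18 lower) or Ctrl replicate 2 (4 and 71). Leaving out Ctrl replicate 3 or DPP3_KO replicate 1, 2 or 3 gave 136, 146, 141 and 123 higher and 4096, 3163, 4993 and 1596 lower. Ctrl replicate 3 correlated at 0.916 and 0.923 with Ctrl replicates 1 and 2, against 0.957 between those. The counts therefore do not show that Ctrl replicates 1 and 2 carry the changes. After median-of-ratios scaling, leaving out Ctrl replicate 1, 2 or 3 gave 17, 41 and 47 higher and 15, 55 and 25 lower genes, and leaving out DPP3_KO replicate 1, 2 or 3 gave 174, 18 and 48 higher and 167, 6 and 15 lower. Camera called 14 lists up and 9 down of 45 as deposited, and 11 up and 13 down after median-of-ratios scaling. As deposited 0 of them were called with an estimated correlation (lowest adjusted p = 0.222, with 5 lists at an unadjusted p under 0.05), and fry, which tests movement in 1 direction without comparing lists with other genes, called 3 up and 18 down as deposited, and 5 up and 3 down after median-of-ratios scaling.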

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

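Rescaling without Scgb1a1, removing the length trend and leaving out samples after median-of-ratios scaling were chosen after seeing the data. The number of higher genes, 216, stayed within 1.5 times under most alternatives, but was 327 after quantile normalization, 141 without Scgb1a1 in the total, 353 at an adjusted p under 0.1, and 1 to 146 with a sample left out (lowest without Ctrl replicate 1). The number of lower genes, 5321, was 3093 without a filter, 139 after median-of-ratios scaling, 140 after quantile normalization, 421 without Scgb1a1, 92 with the length trend removed, 2720 at an unadjusted p under 0.05 with a log2 change of at least 1, and 18 to 4993 with a sample left out. Median-of-ratios scaling, with or without the length trend, and quantile normalization centre the genes, which by construction removes the shift of -0.60, rescaling without Scgb1a1 left a median of -0.33, and leaving out a sample leaves fewer samples; the other causes were not tested. After median-of-ratios scaling, leaving out a sample gave 17 (without Ctrl replicate 1) to 174 higher (main 304) and 6 (without DPP3_KO replicate 2) to 167 lower genes (main 139). Camera's 23 lists became 0 with an estimated correlation and 21 to 27 under the others. The replicate block gave 212 higher and 4734 lower genes and 24 lists. With it camera also called the alveolar type 2 and dendritic cell lists (adjusted p = 0.00536 and 0.0111) and no longer the immediate early list (0.201). Same-numbered samples correlated at 0.271, -0.206 and 0.147, not every sample with its own number best. The numbers thus showed no clear pairing, but so few samples cannot exclude one. Of the named genes, 13 changed sign after median-of-ratios scaling: Rpl3 (0.013), Rpl30 (0.025), mt-Nd3 (0.072), Ndufa9 (0.12), Sdha (0.00042), Ndufb2 (0.014), Hdc (0.063), Krt19 (0.23), Gpm6a (0.20), Klf6 (0.049), Keap1 (0.052), Nfe2l2 (0.21) and Rap1a (0.10). After quantile normalization 5 did, Ndufa9 (0.073), Gpm6a (0.22), Keap1 (0.090), Nfe2l2 (0.061) and Dpp3 (0.013), and with the length trend removed 10 did, Sdha (0.036), Lipe (0.074), Hdc (0.027), Krt19 (0.041), Gpm6a (0.27), Klf6 (0.21), Nfe2l2 (0.18), Rapgef3 (0.095), Rap1gap (0.16) and Rap1a (0.064). Trem1 ranged from -1.23 to 0.056 and Ly6g from -1.63 to 0.13 with a sample left out, both above 0 without DPP3_KO replicate 1. The neutrophil list's median minus that of all genes ranged from -0.15 to 1.39 with a sample left out, and the immediate early list's was -0.16 without a filter. Median-of-ratios scaling ended the calls of 60 named genes, and leaving out Ctrl replicate 1 or 2 those of 93 and 85; pseudocounts of 0.1 and 5 ended 0. With a sample left out, camera no longer called antigen presentation (adjusted p = 0.0575 without Ctrl replicate 1, 0.0727 without DPP3_KO replicate 2), mesothelium (0.222 without Ctrl replicate 3), smooth muscle and immediate early genes (0.0681 and 0.266 without Ctrl replicate 3, 0.125 and 0.154 without DPP3_KO replicate 1), NF-kB (0.107 without DPP3_KO replicate 2) and ribosomal protein genes (0.117 without DPP3_KO replicate 3). The depth is unknown, so it cannot be said which low values were poorly measured.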

Other observations

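The tests of the airway and alveolar pattern, the removal of the length trend, and the tests of the share of loci, the host variant and the outside source for the pseudogenes were chosen after the results were seen; those of matched random lists, endothelial members and the olfactory receptor sum were set before.

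Neutrophil and acute-phase transcripts varied widely between libraries of the same group. The calprotectin gene S100a8 stood at 965, 1766 and 17949 TPM in Ctrl replicates 1 to 3 and 394, 10614 and 4826 TPM in DPP3_KO replicates 1 to 3, and Saa3, the gene of an acute-phase serum amyloid, at 156, 148 and 9904 TPM and 102, 21047 and 7931 TPM. Lcn2, the gene of neutrophil lipocalin, stood at 607, 481 and 3617 TPM and at 162, 2050 and 1497 TPM. The neutrophil score averaged 6.67 ± 1.52 in Ctrl and 6.56 ± 1.70 in DPP3_KO, and the second principal component, with 22.8% of the variance, ran from -57.7 in Ctrl replicate 3 to 46.4 in DPP3_KO replicate 1. Gm9843, an unnamed model, was listed at 0 in each Ctrl library and stood at 176, 362 and 353 TPM in DPP3_KO.

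Camera called the ciliated, club cell and striated muscle lists up and the alveolar type 1, capillary and alveolar macrophage lists down in DPP3_KO at the preset correlation, 0 of them with an estimated correlation. A larger share of Scgb1a1 moves the other genes of a library alike. The ciliated minus alveolar type 1 score rose by 2.67 from -3.34 ± 0.43 (SD, n = 3) to -0.67 ± 0.64, without overlap. These 2 lists were chosen after they were seen to move apart, so the score restates the pattern. With Scgb1a1 left out of the total, the ciliated and alveolar type 1 medians were still 1.37 and -1.64. This argues against its share as the whole cause. Less alveolar tissue in the pieces would lower the alveolar cell types alike, but the alveolar type 2 minus type 1 score differed by 0.83 (0.66 ± 0.28 in Ctrl, 1.48 ± 0.46 in DPP3_KO) and the alveolar macrophage minus type 2 score by -1.34 (-3.39 ± 0.12 and -4.73 ± 0.42), both without overlap. The first difference was 2.17 pooled SD and the second 4.35. Both scores compare lists whose changes had already been seen. The lists also share genes with those of other cells, such as Pdpn with lymphatic endothelium and Car4 with aerocytes. The scores therefore cannot decide whether alveolar tissue was lost evenly, and an even loss stays open. An uneven choice of tissue piece, to which the higher striated muscle list (median 1.17) would point, and an effect of the tumour genotype stay open too.

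The RAP1 core list had a lower median than other genes, and camera's call of it did not hold with an estimated correlation (adjusted p = 0.182 after median-of-ratios scaling). Long genes were lower in DPP3_KO after median-of-ratios scaling (Spearman rho -0.332 across genes, which are not independent replicates), but among 10000 random lists matched on length and expression, with a median of -0.19, the RAP1 core median of -0.39 lay at percentile 0.0900. Random lists lack the correlation of a pathway, so this percentile overstates the distance; with the length trend removed the list stood at -0.26 (camera adjusted p = 0.00604, and adjusted p = 0.229 with an estimated correlation). Its 8 members known from endothelium were lower than the other 38 by -0.43 (medians -0.74 and -0.31, one-sided permutation p = 0.0145 with 100000 resamples), as fewer endothelial cells would give. The resamples shuffled member genes, which are not independent replicates, so this p measures spread between genes and not between samples. The other members alone also lay below other genes at the preset correlation (camera unadjusted p = 0.000584, and unadjusted p = 0.0745 with an estimated correlation). Fewer endothelial cells cannot be told apart from a change within cells here, because no value measures expression per cell type.

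Processed pseudogenes were found in Ctrl and near 0 in DPP3_KO: 47 had at least 1 TPM in every Ctrl library and at most 0.1 of the Ctrl mean in every DPP3_KO library, against 2 the other way round. Summed TPM of 1413 olfactory receptor genes, silent in lung, was higher in every Ctrl library than in every DPP3_KO library (61.4 ± 6.06 and 35.9 ± 9.88, ratio 1.71), as genomic DNA in Ctrl would give, but after median-of-ratios scaling the groups overlapped (48.7 ± 7.14 and 44.7 ± 10.3, ratio 1.09). The criterion was met by 0 of the 1413 and by 47 of 10216 processed pseudogenes (two-sided Fisher's exact p = 0.00537). It had been drawn from the pseudogenes, so this p overstates the contrast. DNA covers loci about evenly, so DNA at the 47 pseudogenes' median Ctrl mean of 6.49 TPM would have raised the olfactory receptor genes alike. Their Ctrl sum of 61.4 TPM over 1413 genes argues against DNA as the whole source. A variant of the host mice in each pseudogene, if shared by the Ctrl mice, would give the Ctrl libraries similar levels. The median ratio of highest to lowest Ctrl library was 6.39, against 1.80 at the 95th percentile of random sets of the 291 other pseudogenes. The random sets were not matched on expression, and whether the Ctrl mice shared variants is not known. A host variant is therefore not excluded. The comparison covers the pseudogenes only. The Nnt entry named above went the other way, at 0.02, 0 and 0 TPM in Ctrl and 9.41, 5.31 and 6.37 in DPP3_KO. A host variant was not tested for it or for the groups in general. In 72.3% of the 47 (34), Ctrl replicate 3 was highest and replicate 2 lowest, against 18.6% of the others, as 1 outside source of reads in different amounts would give. Several of the 47 are ribosomal protein pseudogenes. The ribosomal protein score had the same order, at 9.55, 9.45 and 9.42 in Ctrl replicates 3, 1 and 2, with group means of 9.48 in Ctrl and 9.41 in DPP3_KO. Reads shared with parent genes were not tested, and Gm8783 and Gm15801 have identical values. The order alone therefore does not show an outside source. Human tumour RNA in Ctrl lungs and a difference in how the groups were processed are hypotheses for such a source, not tested here.

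The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 216 higher and 5321 lower genes, and the highest other split gave 17 in 1 direction and 2 in the other, so 1 split gave as many of each, comparing the larger and the smaller count and not the direction; for lists called by camera the real value was 23 and the highest other 29, with 7 splits at 23 or more.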
